A study of Homo sapiens with 6 samples.

How the data were processed

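HepG2 cells carrying a control or an HNF4A siRNA had been exposed to TGF-beta (3 ng/ml) over 0, 1.5 or 24 h, and their total RNA was labelled with biotin and hybridised to 6 Affymetrix arrays, 1 per combination, per the labels. The deposited values are intensities on a linear scale, MAS5 signals that the authors computed with MAS5 version 5.0 and GCOS, per the submitters' processing notes. MAS5 combines the probe pairs of a probe set into 1 signal. The mean after trimming 2% at each end was 100 on every array, the mark of MAS5 global scaling, and the highest signals lay between 11258 and 13116. Detection calls and probe-level files were not used here.

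All 54675 probe sets were read, and 62 control probe sets served only as checks. Gene names came from a table that pairs the probe sets with the platform annotation. It gave 1 gene symbol for 41097 probe sets, several for 1801, which were named by none, and none for 11777, the control probe sets included. Through their Entrez identifiers 41043 of the single-symbol probe sets were found in a RefSeq gene table, and no symbol needed an update. Of the 19775 genes 10523 had more than 1 probe set, and a gene's probe set was the one with the highest mean signal over the 6 arrays. Among called genes with other probe sets above the floor, 957 of 1060 other probe sets (90.3%) had the same direction for the siRNA and 1600 of 1773 (90.2%) for TGF-beta at 24 h. The HNF4A signal planned as the check of the knockdown is not reported here, nor are a few other planned genes, which were left out of their lists.

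Signals were used as deposited, with no further scaling. Signals below the floor, 12.9, the median of all signals of the 6 arrays, were set to it, and log2 was taken. The 11921 genes whose mean signal exceeded the floor entered the fits. Pearson correlations between arrays were 0.946 to 0.983.

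Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit with siRNA and time as terms gave the siRNA difference over 3 times and the TGF-beta differences at 24 h and at 1.5 h over both siRNAs, with 2 residual degrees of freedom and 12.6 prior degrees of freedom. Since no group had a replicate, the residual is the disagreement of a difference between times or between siRNAs, so a true dependence of the siRNA effect on time counts as error. A further fit added a term for the siRNA effect at 24 h against its mean at 0 and 1.5 h, with 1 residual and 8.56 prior degrees of freedom. Genes at a 2-fold difference between single arrays were counted without a test, as were the genes with the larger TGF-beta response in either arm, selected on the average of the arms. An siRNA can lower other transcripts than its target, and with 1 siRNA label per arm such effects were not separated.

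Before the data were examined 24 gene lists were fixed, with markers of blood, endothelial and fibroblast cells among them. Some genes stand in more than 1 list, so counts of different lists are not independent. Each list was described by its measured members, the number that passed over all genes and adjusted over the list alone, and the percentile of its median among 10000 random lists of the same size drawn from 20 bins of mean expression. Genes named were fixed by a rule at the same time. It took SMAD7, SKIL, ID1 and MIXL1, and for each of 4 contrasts the 10 highest and 10 lowest differences of genes above the floor on all arrays of the contrast and with 1 sign across times or arms (no sign rule for the difference between arms). It also took up to 5 genes per direction with a signal at the floor and up to 4 members of each list with the largest differences. The 4 contrasts were the siRNA, both TGF-beta times in siControl, and the difference between arms at 24 h. Genes called at 1.5 h, called members of lists beyond those 4 and CCNE1 were named after their values were seen.

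The limma step was tested on simulated data with 200 of 11921 genes changed, at the means of these genes and spreads from limma's fit. For a 2-fold change it recovered 85% of changed genes for the siRNA, 76% for TGF-beta at 24 h and 72.5% at 1.5 h. For a 4-fold change it recovered 91.5%, 92% and 91.5%. False calls numbered 7, 0 and 4 at 2-fold and 14, 5 and 19 at 4-fold. The simulated noise was normal, with spreads that limma's prior had already adjusted, so recovery in real data may be lower. Alternatives were quantile normalization, scaling to the median, floors at the 40th and 60th percentiles, a pseudocount equal to the floor, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, no filter on dim genes, eBayes without the trend and leaving out each pair of arrays of 1 time. A floor at the 75th percentile, leaving out the siControl 0 h array and the 1.5 h array as the reference for 24 h were chosen after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.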

Results

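Gene expression was measured in HepG2 cells, a human hepatoblastoma line that keeps many functions of hepatocytes, after transfection with an siRNA, a short double-stranded RNA that lowers the transcript it matches. Cells received a control siRNA (siControl) or an siRNA against HNF4A (siHNF4A), a nuclear receptor that drives liver genes, and then TGF-beta, a cytokine that acts through Smad transcription factors. TGF-beta was given at 3 ng/ml for 0, 1.5 or 24 h. Each of the 6 combinations was hybridised to 1 Affymetrix array, so no group had a replicate. No array at 1.5 or 24 h without TGF-beta was used here, so differences from 0 h do not separate TGF-beta from elapsed time in culture. The deposited MAS5 signals, scaled intensities of 54675 probe sets per array, had a median of 12.4 to 13.3 per array. Between 49.1% and 50.7% of the probe sets of an array lay above 12.9, the median of all signals, which served as the floor. Differences below are on the log2 scale with limma's standard error, and "at least" marks those in which a signal at or under the floor was set to it. The number of arrays limits the precision of every value.

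The siControl 0 h array stood apart in a set of control probes. The control probe set whose name begins with AFFX-HUMRGE and that lies at the 5' end read 8600 there, against 69.8 to 736.5 on the other 5 arrays. GAPDH control probe sets gave a 3'/5' signal ratio of 0.888 on that array and 0.946 to 0.977 on the others, and ACTB control probe sets gave 1.17 to 1.28 over the 6 arrays. Counts below that moved by more than 1.5-fold without that array are given both ways. Fits without that array or without a pair of arrays had 1 residual degree of freedom. They rest largely on limma's prior for the spread, so a call lost or gained in them can also reflect that prior. For the siRNA, leaving out that array gives the same difference as leaving out the 0 h pair. The siHNF4A 0 h array then has no partner, so these are not separate checks. The level of HNF4A itself was not analysed here, so the siRNA labels were not checked against it.

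The comparison of siRNAs asked which genes of HepG2 cells depend on HNF4A. CYP4F3, a fatty acid hydroxylase, fell by at least 2.70 ± 0.25 over the 3 times, from signals of 128 to 150 in siControl to 10.6 to 34.7 in siHNF4A. DIO1, the deiodinase that makes active thyroid hormone, fell by 2.30 ± 0.21, and FABP1, the liver fatty acid binding protein, fell by 1.71 ± 0.21. SLC51B, a subunit of a bile acid exporter, fell by 1.86 ± 0.22, and SOAT2, which esterifies cholesterol, fell by 1.74 ± 0.19. In the drug metabolism list 11 of 24 measured genes fell, none rose and 13 did not pass. GSTA1, a glutathione transferase (at least -1.99), the aldo-keto reductase AKR1B10 (-1.44) and the alcohol dehydrogenase ADH4 (-1.22) were among the 11. Adjusted over the list alone, 13 fell. The list's median of -0.54 lay below all 10000 random lists of like expression, as a description of these arrays.

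Of 28 measured genes held as textbook HNF4A targets, 8 fell, 1 rose and 19 did not pass, and adjusted over the list alone 14 fell and 1 rose. CIDEC, a lipid droplet protein, fell by 1.61 ± 0.18, the liver pyruvate kinase PKLR by at least 1.31 ± 0.29, the apolipoprotein APOC3 by 0.89 ± 0.14 and the clotting factor F7 by 0.87 ± 0.19. The gene that rose was HAMP (0.46 ± 0.11), which encodes the iron hormone hepcidin. Without the siControl 0 h array 6 fell and none rose. The median of the list was -0.41, below all 10000 random lists. In the coagulation and complement list 5 of 29 fell and 2 rose, or 3 and 1 without the siControl 0 h array. Adjusted over the list alone 8 fell and 3 rose. Antithrombin (SERPINC1) fell by 1.02 ± 0.14, while C5 rose by 0.61 and C3 by 0.44. Secreted plasma proteins moved both ways, with 6 of 42 falling and 8 rising, or 7 and 5 without that array, and 8 each way adjusted over the list alone. LEAP2 fell by 1.48 ± 0.23 and haptoglobin (HP) by 0.87 ± 0.23, whereas the fibrinogen genes FGB, FGA and FGG rose by 0.74, 0.42 and 0.38. FGA had -0.14 (not passing) when probe sets ending in _x_at or _s_at were left out. Without the 0 h pair, or its siControl array alone, F7 (-0.78), HAMP (0.36), C3 (0.26) and FGA (0.26) did not pass. Without the 1.5 h pair C3 had 0.69 and passed, PKLR (-0.96), HAMP (0.41), FGA (0.43) and FGG (0.28) did not, and without the 24 h pair APOC3 (-0.74), F7 (-0.95), C3 (0.37), HP (-0.34), FGA (0.56) and FGG (0.49) did not. In bile acid and lipoprotein metabolism 3 of 20 genes fell and none rose, or 1 without that array, and 6 fell adjusted over the list alone.

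Some cell cycle genes fell with the siRNA as well. Of 43 measured, 13 fell, none rose and 30 did not pass, and 19 fell adjusted over the list alone. The replication licensing factor CDT1 fell by 0.91 ± 0.19, the mitotic kinase AURKB by 0.74 ± 0.16 and the proliferation marker MKI67 by 0.66 ± 0.15. Among 20 measured interferon-response genes 4 fell, 1 rose and 15 did not pass, and 10 fell and 1 rose adjusted over the list alone. Without the siControl 0 h array 7 fell and 1 rose. IFIT1, an antiviral RNA-binding protein, fell by at least 1.83 ± 0.26, ISG15 by 0.66 and IRF9 by 0.63, and IFIT5 rose by 0.63. IFIT5 (0.72) did not pass without the 0 h pair, and AURKB (-0.77), MKI67 (-0.64), IRF9 (-0.47) and IFIT5 (0.48) did not without the 1.5 h pair. CDT1 (-0.56), AURKB (-0.56), MKI67 (-0.55), ISG15 (-0.64), IRF9 (-0.60) and IFIT5 (0.68) did not without the 24 h pair. The medians of both lists, -0.35 and -0.59, lay below all 10000 random lists.

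Some acute-phase, immediate-early and progenitor genes rose with siHNF4A. IL11, a cytokine of the interleukin-6 family, rose by 2.94 ± 0.22, and the neutrophil chemokine CXCL8 rose by 2.22 ± 0.24. The adhesion molecule ICAM1 rose by 1.39 ± 0.15, and 4 of the 10 measured acute-phase and inflammatory genes rose, with none falling. Adjusted over that list alone 4 rose and 1 fell. Of 14 immediate-early genes, 6 rose and none fell, and 9 rose adjusted over the list alone. They included the phosphatase DUSP1 (1.18 ± 0.20), EGR1 (0.81 ± 0.23) and MYC (0.58 ± 0.12). The list's median was 0.26 at 0 h, 0.16 at 1.5 h and 1.00 at 24 h, and DUSP1 had 0.73 and still passed without the 24 h pair. Of 15 hepatoblast, progenitor and biliary markers, 4 rose and none fell, and 8 rose and 1 fell adjusted over the list alone. CD24 rose by 0.96 ± 0.08, SOX4 by 0.75 ± 0.11 and KRT19 by 0.57 ± 0.09. The CDK inhibitors CDKN2B (1.10 ± 0.20) and CDKN1B (0.74 ± 0.10) rose, 2 of the 5 measured, or 3 adjusted over the list alone. Among 32 TGF-beta feedback and direct target genes 7 rose and none fell, and 12 rose adjusted over the list alone. The co-repressor TGIF1 rose by 0.75 ± 0.11 and the follistatin-like FSTL3 by 0.76 ± 0.17. The receptor TGFBR2 rose by 0.53 ± 0.09, and MIXL1, a Smad target of early mesoderm, fell by 1.26 ± 0.24. FSTL3 (0.62) did not pass without the 0 h pair or its siControl array, nor EGR1 (1.07) and MIXL1 (-1.11) without the 1.5 h pair. Without the 24 h pair EGR1 (0.26), MYC (0.38), KRT19 (0.43), CDKN2B (1.05), FSTL3 (0.78) and TGFBR2 (0.46) did not pass.

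In limma, with time as a block and Benjamini-Hochberg adjustment, 465 genes rose and 496 fell with siHNF4A among 11921 tested, and the smallest adjusted p was 6.2e-06. Of these, 79 rose and 119 fell by at least 2-fold. FAM3C (1.83 ± 0.13) and AIDA (1.78 ± 0.14) had the smallest p-values with IL11 and the ribonuclease inhibitor RNH1, at -2.00 ± 0.16. The count of 961 was 227 with the mean of a gene's probe sets, 45 without limma's intensity trend, 0 without the filter on dim genes, 578 without the 1.5 h pair and 242 without the 24 h pair. The p-values set the siRNA difference over the 3 times against a spread with 2 residual and 12.6 prior degrees of freedom. That spread rests more on limma's prior from other genes than on how far a gene's own difference repeated. EGR1 was called, though its difference was 1.07 without the 1.5 h pair and 0.26 without the 24 h pair. The labels do not say whether the arrays of an siRNA came from 1 transfection. Genes at 2-fold between single arrays, with no replicate, numbered 379 at 0 h (180 higher in siHNF4A), 586 at 1.5 h (188 higher) and 654 at 24 h (281 higher). The central 95% of all genes' differences ran from -0.89 to 0.87, from -1.07 to 0.87 and from -1.05 to 0.96. The 2-fold counts were 786, 1075 and 1142 with the floor at the 40th percentile and 107, 155 and 184 at the 75th, and 115, 177 and 200 genes had a signal above 100.

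**Figure D1:**
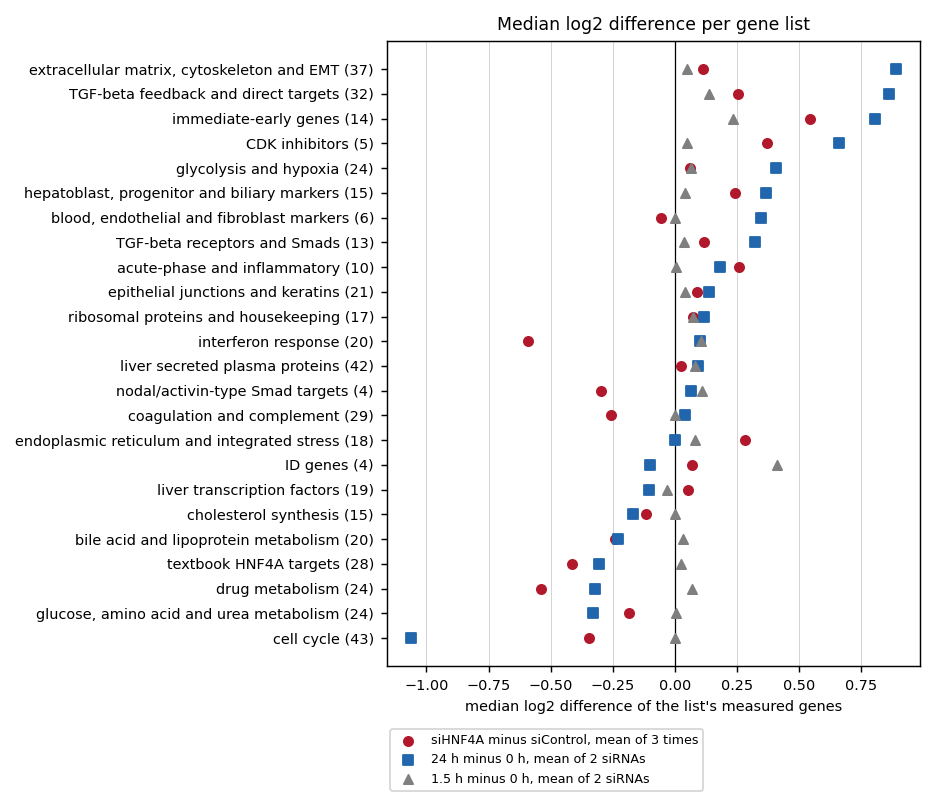
Median log2 difference of the measured genes of each list (number measured in parentheses) for siHNF4A minus siControl over 3 times (circles), 24 h minus 0 h of TGF-beta over both siRNAs (squares) and 1.5 h minus 0 h (triangles). Cell cycle genes lie lowest at 24 h (-1.06) and interferon-response genes lowest for the siRNA (-0.59); the medians of the ribosomal and housekeeping list, 0.07 to 0.12, turn below 0 with quantile normalization.

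The early comparison asked which genes differed after 1.5 h with TGF-beta. JUNB, a subunit of the AP-1 transcription factor, rose by 2.93 ± 0.26 on average over the siRNAs (2 arrays at each time), from signals of 35.5 to 347 in siControl and 59.8 to 355 in siHNF4A. SMAD7, which encodes the inhibitory Smad that feeds back on the receptor, rose by 1.17 ± 0.15, and the zinc finger gene KLF10 rose by 1.24 ± 0.13. GADD45B (2.07 ± 0.22), RND1 (2.27 ± 0.26), DDIT4, an inhibitor of mTOR signalling (2.05 ± 0.18), and the endothelin gene EDN1 (1.62 ± 0.17) also rose. BHLHE40 (1.64), DLX2 (1.40) and the Notch target HES1 (1.27) were the other genes that rose. MYC fell by 0.94 ± 0.14, from 1773 to 857 in siControl and from 2140 to 1206 in siHNF4A, and TMEM184C fell by 1.24 ± 0.18. At 24 h SMAD7, KLF10 and MYC had log2 differences from 0 h of -0.38, -0.04 and 0.03, none of which passed the test. EDN1 went on to 2.97 ± 0.17 at 24 h. DLX2 (1.40), HES1 (1.27) and TMEM184C (-1.24) did not pass without the 24 h pair, and TMEM184C (-1.04) did not without the siControl 0 h array.

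Among the 32 measured TGF-beta feedback and direct targets 5 rose at 1.5 h and none fell, or 9 rose adjusted over the list alone, and the list's median of 0.14 lay above all 10000 random lists. None of the ID genes, BMP-type Smad targets, passed over all genes. Adjusted over the list of 4 alone 3 rose, and ID1 was 0.57 ± 0.11 higher. Without the siControl 0 h array 1 of the 4 rose. Of 14 immediate-early genes 1 rose and 1 fell, or 3 and 1 without that array, and 5 rose and 2 fell adjusted over the list alone. The 1 that rose, JUNB, is also 1 of the 5 feedback and direct targets above. SKIL was 0.59 ± 0.13 higher at 1.5 h (limma adjusted p = 0.25), MIXL1 was 1.09 ± 0.29 higher (0.63), and the cytokine signalling inhibitor SOCS3 was at least 1.77 ± 0.35 higher (0.12). Of the other lists, 1 gene of the endoplasmic reticulum and integrated stress list, DDIT4, passed, also adjusted over the list alone. So adjusted, 2 of 10 acute-phase and inflammatory genes and 1 of 4 nodal and activin targets rose, and 1 of 6 blood, endothelial and fibroblast markers fell.

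In limma 10 genes rose and 2 fell at 1.5 h of 11921 tested, with the smallest adjusted p at 7.7e-05, and 364 genes had an unadjusted p under 0.05 where chance alone gives 596. The count of 12 was 26 without the siControl 0 h array, which kept 11 of the 12 (TMEM184C was lost), and 0 with the mean of a gene's probe sets, without the intensity trend and without the filter on dim genes. Between single arrays 211 genes differed by at least 2-fold in siControl (122 higher) and 249 in siHNF4A (68 higher). These counts were 639 and 652 with the floor at the 40th percentile and 19 and 18 at the 75th, and 24 and 22 of the genes had a signal above 100. Across the genes tested the 1.5 h differences of the siRNA arms had a Pearson r of -0.07, and genes are not independent replicates.

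**Figure D2:**
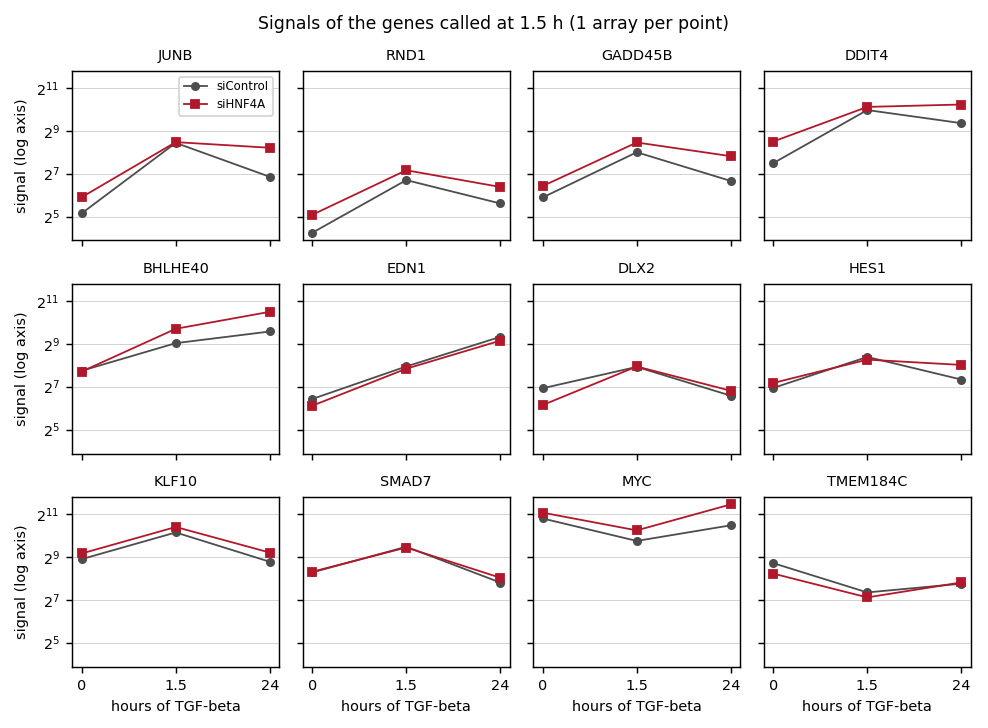
Signals (log axis) of the 12 genes called at 1.5 h against hours of TGF-beta, with 1 array per point, in siControl (circles) and siHNF4A (squares). JUNB rises from 35.5 to 347 in siControl and from 59.8 to 355 in siHNF4A between 0 and 1.5 h; MYC and TMEM184C are the 2 that fall.

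The late comparison asked which genes differed after 24 h with TGF-beta, a difference that could not be separated from 24 h of culture. The extracellular matrix and cytoskeleton genes rose together with TGF-beta targets. COL1A1, a fibrillar collagen, rose by 2.62 ± 0.21 on average over the siRNAs (2 arrays at each time), the actin-binding TAGLN by 2.14 ± 0.15, the protease inhibitor TIMP1 by 2.10 ± 0.20 and the urokinase PLAU by 1.77 ± 0.33. Of 37 measured genes in that list 22 rose, none fell and 15 did not pass, and 26 rose adjusted over the list alone. The Smad-binding feedback gene PMEPA1 rose by at least 3.29 ± 0.36, CDKN2B by 2.57 ± 0.25 and SKIL by 1.02 ± 0.13, among 19 of 32 feedback and direct targets that rose, with none falling. Adjusted over the list alone 21 rose and 1 fell. The axon guidance ligand SEMA3C rose by at least 3.71 ± 0.30, the calcium-binding S100A3 by 2.88 ± 0.21 and the protease KLK6 by 2.95 ± 0.30. IL11 rose by 3.11 ± 0.26, from 28.5 to 156.5 in siControl and from 150 to 2027 in siHNF4A.

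Of 14 immediate-early genes 9 rose and none fell, and 10 rose adjusted over the list alone, with IER3 at 1.83 ± 0.11 and EGR1 at 1.92 ± 0.28. Glycolysis and hypoxia genes rose in 9 of 24 cases with none falling, or 11 adjusted over the list alone and 8 with 1 falling without the siControl 0 h array, including NDRG1 (1.54 ± 0.19) and the glucose transporters SLC2A3 (1.04 ± 0.11) and SLC2A1 (0.97 ± 0.13). Epithelial junction and keratin genes did not fall as a list. CDH1, the epithelial cadherin, rose by 1.85 ± 0.17, from 197 to 652.5 in siControl and from 132 to 521.5 in siHNF4A, and CLDN6 rose by 1.14 ± 0.26. Of 21 measured 7 rose and 1 fell, the connexin GJB1 (-0.80 ± 0.20), and adjusted over the list alone 8 rose and 1 fell. Without the siControl 0 h array 6 rose and 2 fell. Of 15 hepatoblast, progenitor and biliary markers 6 rose and none fell, or 7 adjusted over the list alone, with SOX4 at 1.40 ± 0.13 and PROM1 at 1.32 ± 0.21. Among receptors and Smads the type II BMP receptor BMPR2 rose by 1.25 ± 0.18, with ACVR1 and TGFBR2 the other 2 of 13 to rise, or 1 without that array, when ACVR1 (0.64) and TGFBR2 (0.42) did not pass, and 4 adjusted over the list alone.

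Cell cycle genes fell almost throughout. Of 43 measured, 42 fell in limma over all genes and 43 adjusted over the list alone, and the median of -1.06 lay below all 10000 random lists. The transcription factors E2F1 (at least -2.66 ± 0.27) and E2F2 (-2.13 ± 0.25) fell, MKI67 fell by 1.41 ± 0.18, and the replication factor CDC6 had -2.00 ± 0.17. CCNE1 (-0.53 ± 0.18, limma adjusted p = 0.0563) was the gene that did not pass over all genes, though it did without the 1.5 h pair (-0.53, 0.0489). CDKN2B, CDKN1A (0.72 ± 0.15) and CDKN2A (0.66 ± 0.21) rose, 3 of 5 CDK inhibitors and 3 adjusted over the list alone, and CDKN2A (0.82) did not pass without the siControl 0 h array.

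Several liver metabolism genes fell at 24 h. AKR1B10 fell by 2.40 ± 0.21, DDC, the decarboxylase of aromatic amino acids, by 2.35 ± 0.19, ADH4 by 1.92 ± 0.21 and the proline pathway enzyme PRODH2 by 1.72 ± 0.21, and GSTA1 had at least -1.97 ± 0.26. The liver transcription factor CEBPA fell by 1.40 ± 0.16. Of 24 drug metabolism genes 6 fell and 2 rose, the same numbers as adjusted over the list alone. Of 24 glucose, amino acid and urea genes 7 fell and 1 rose, also adjusted over the list alone, or 4 and 1 without the siControl 0 h array. Of 28 textbook HNF4A targets 6 fell and 2 rose, or 7 and none without that array, and 8 fell and 4 rose adjusted over the list alone. HAMP fell by 1.24 ± 0.14 and the lipoprotein transfer gene MTTP by 1.23 ± 0.22. Of 20 bile acid and lipoprotein genes 5 fell and 3 rose, or 4 and 1 without that array, and 6 and 3 adjusted over the list alone. Plasma protein genes went both ways, with 10 of 42 falling and 6 rising, or 12 and 3 without that array, and 11 and 8 adjusted over the list alone. SERPINA3 (1.59 ± 0.12) and IGFBP1 (0.89 ± 0.13) rose, and FGA fell by 1.02.

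In limma 861 genes rose and 932 fell at 24 h of 11921 tested, with the smallest adjusted p at 2.5e-07, and 340 rose and 271 fell by at least 2-fold. The count of 1793 was 806 with the mean of a gene's probe sets, 457 without the intensity trend and 1 without the filter on dim genes. FOLR1 rose by 1.78 ± 0.44, but its 0 h signal in siControl, 101, stood against 617 to 1215 on the other 5 arrays. Without that array FOLR1 (0.43) did not pass. Single arrays differed by at least 2-fold for 695 genes in siControl (380 higher) and 1112 in siHNF4A (555 higher). The counts were 239 and 461 with the floor at the 75th percentile, and 264 and 489 of the genes had a signal above 100.

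The comparison of the arms asked whether the TGF-beta response differed when HNF4A was targeted. TAGLN and EDN1 had 24 h differences of 2.07 and 2.90 in siControl and 2.22 and 3.04 in siHNF4A, and E2F1 had -2.44 and at least -2.89. Larger gaps were seen for COL1A1 (2.18 in siControl, 3.06 in siHNF4A), TIMP1 (1.51 in siControl, 2.69 in siHNF4A), EGR1 (1.09 and 2.74), DUSP1 (0.77 and 2.19) and CXCL8 (1.34 and 3.07). TXNIP, which binds thioredoxin and limits glucose uptake, fell from 640 to 515 in siControl, a difference of -0.31, and from 1054 to 167 in siHNF4A, a difference of -2.66. DPP4 went from 210 to 872 in siControl and from 243 to 170 in siHNF4A.

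These gaps, taken from 0 h, were not themselves tested. The limma term for a different siRNA effect at 24 h sets it against its mean at 0 and 1.5 h. That term called 0 of 11921 genes, with 543 at an unadjusted p under 0.05 and 596 by chance. TXNIP had its smallest adjusted p (0.0703, -2.28 ± 0.25). In simulated data that fit recovered 34% of genes changed by 2-fold and 82.5% of those changed by 4-fold, with 11 and 15 false calls. It called 4 genes with the floor at the 40th percentile, 24 with a pseudocount in place of the floor and 639 without the filter on dim genes. The fit has 1 residual degree of freedom. Its prior degrees of freedom were 8.56 as reported, 13.6 with that floor and 47.7 with the pseudocount, so a higher count can reflect the prior. Adjusted over the list alone, the term was positive and passed for 7 of 14 immediate-early genes, 2 of 37 matrix genes and 2 of 10 acute-phase and inflammatory genes. A positive term is not always a larger response, as CCL20 had 24 h differences of -0.41 in siControl and 0.80 in siHNF4A. On another measure, the 24 h minus 0 h response in siHNF4A minus that in siControl, the acute-phase and inflammatory list went the other way. Its median was -0.46, with 7 of 10 genes below 0. The immediate-early and matrix lists had medians of 0.73 and 0.15 on that measure, with 14 of 14 and 25 of 37 genes above 0. The cell cycle list had -0.36, with 37 of 43 genes below 0. The term was negative and passed for 2 of 42 plasma protein genes and for 1 gene each of the bile acid and lipoprotein, drug metabolism, and endoplasmic reticulum and integrated stress lists. Among 367 genes that were at least 2-fold higher at 24 h on the average of the arms, 256 had the larger change in siHNF4A, with median sizes of 1.15 in siControl and 1.44 in siHNF4A. Among the 283 that were at least 2-fold lower, 214 did, with 1.09 and 1.38. The share turned over when genes were selected on siControl alone, with 135 of 371 and 102 of 310. At 1.5 h 12 of 26 genes on the higher side and 8 of 17 on the lower side had the larger change in siHNF4A. Across genes the arms had a Pearson r of 0.595 at 24 h (Spearman 0.55).

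**Figure D3:**
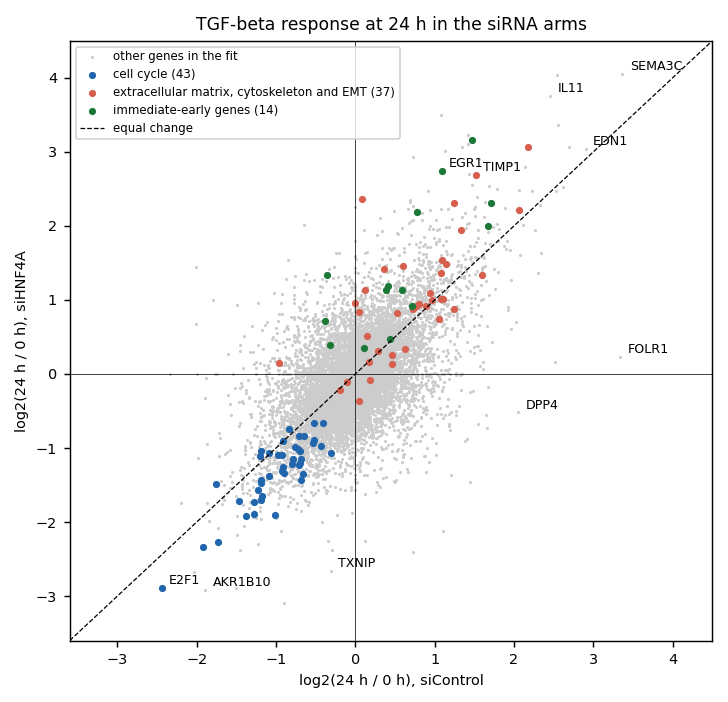
Log2(24 h / 0 h) of every gene tested in siControl (x axis) and siHNF4A (y axis), with 1 array per time and arm; colours mark 3 gene lists and the dashed line marks equal change. Of the genes at least 2-fold from 0 h on the average, 256 of 367 higher and 214 of 283 lower have the larger change in siHNF4A, and TXNIP (-0.31, -2.66) lies far below the line.

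The last comparison asked whether siHNF4A and TGF-beta moved the same genes. IL11, CXCL8 and CDKN2B rose with both, and AKR1B10, GSTA1, ADH4, FABP1 and DIO1 fell with both. IGFBP7, a secreted growth factor binding protein, went opposite ways, with -0.83 ± 0.19 for the siRNA and 1.99 ± 0.23 at 24 h, as did CDH1 (-0.54 ± 0.14 and 1.85 ± 0.17) and HAMP (0.46 and -1.24). Their siRNA calls were lost with a pair left out, CDH1's without 0 h (-0.52), 1.5 h (-0.45) or 24 h (-0.65), HAMP's without 0 h (0.36) or 1.5 h (0.41) and IGFBP7's without 24 h (-0.59), as was CDKN2B's (1.05). Of the genes called for both, 154 rose with both and 137 fell with both, where lists drawn independently would share 33.6 and 38.8. Another 19 rose with the siRNA and fell at 24 h, and 21 did the reverse, against 36.4 and 35.8. These contrasts share arrays, in a balance that cancels their noise only if the arrays are equally noisy. Their covariance across genes was 0.0524, against -0.0014 to 0.0012 in 100 simulations of unchanged genes. The simulated noise was drawn independently for each gene. Between the siRNA difference at 1.5 h and the TGF-beta difference at 24 h in siControl, which share none, the Pearson r across genes was 0.162. The covariance of that pair was 0.0383, and unchanged genes gave -0.0026 to 0.0025.

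**Figure D4:**
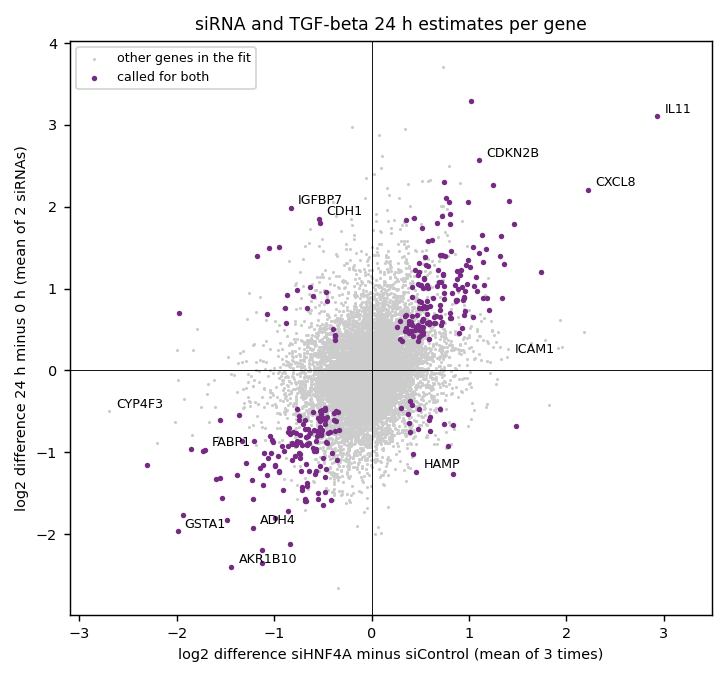
Limma log2 differences of each gene tested for the siRNA (x axis, siHNF4A minus siControl over 3 times) and for 24 h of TGF-beta (y axis, over both siRNAs); dark points were called for both. The upper right holds 154 of them and the lower left 137, against 19 and 21 in the other corners.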

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

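The search for genes with opposite responses in the arms was made after the data were seen. IKBKB-DT, a transcript that lies divergent to IKBKB, went opposite ways at 24 h of TGF-beta. Its log2 difference from 0 h was 1.45 in siControl, from a signal of 13 to 35.4, and -1.46 in siHNF4A, from 40.2 to 14.6. It drew attention because the sole pair of arrays of each arm moved by at least 2-fold in opposite directions, and the difference was not tested by replicates. The limma term for a different siRNA effect at 24 h gave an adjusted p of 0.988 for it. It was the 1 such gene among 10709 measured on all arrays concerned at 24 h, and 5 of 10759 did so at 1.5 h. These signals lie near the floor of 12.9.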

How the results depend on the processing

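The floor at the 75th percentile, the fits without the siControl 0 h array and the 1.5 h reference for 24 h were chosen after seeing the data. The siRNA test was paired by time, with time as its block. Replicates could not be paired, because the labels carry no replicate numbers and each group held 1 array. The HNF4A signal after knockdown, a planned result, was not analysed here. Over all alternatives 107 of the values that answer a comparison stayed within 1.5 times or within their interval, 62 moved beyond it and 2 turned over, as did 585, 8 and 4 list medians. For genes named, 1417 results kept direction and side of the threshold, 375 lost the call, 16 gained it and 5 changed sign. Under quantile normalization and median scaling every count of calls stayed within 1.5 times, and all genes shared with the reported calls kept their direction. The cause was not tested except where fewer arrays or genes entered. Genes called for the siRNA (961 reported), 24 h (1793) and 1.5 h (12) numbered 227, 806 and 0 with the mean of all probe sets, 45, 457 and 0 with eBayes without trend, and 0, 1 and 0 with no filter on dim genes. Of the 45 and 457, 45 and 449 were among those reported. With the mean of all probe sets limma's prior degrees of freedom were 3.62, against 12.6 as reported. The lower counts of that setting can also reflect the prior. There, 2257 of 11240 genes had an unadjusted limma p under 0.05 for the siRNA and 2850 for 24 h. The reported fit had 2552 and 3313 of 11921. The siRNA count was 578 without the 1.5 h pair, 242 without the 24 h pair and 943 without the 0 h pair, and of the genes named 17, 28 and 8 then lost a call. Of those counts 498, 234 and 726 were among the 961 reported. These fits had 1 residual degree of freedom and rest largely on the prior. The 1.5 h count was 26 without the siControl 0 h array, when the siRNA and 24 h counts were 940 and 1431. For the siRNA effect at 24 h (0 reported) 4 genes passed with the floor at the 40th percentile, 24 with the pseudocount and 639 with no filter. The 2-fold counts were higher when dimmer signals entered and lower when they were left out. In the order siHNF4A against siControl at 0, 1.5 and 24 h, then TGF-beta at 1.5 and 24 h in siControl and at 1.5 and 24 h in siHNF4A, the mean of all probe sets gave 201, 318, 385, 102, 420, 115 and 730. The floor at the 75th percentile gave 107, 155, 184, 19, 239, 18 and 461. The floor at the 40th percentile gave 786, 1075, 1142, 639 and 1163 for the leading 5 and 652 for 1.5 h in siHNF4A. The floor at the 60th percentile gave 219, 351, 404 and 77 for the leading 4 and 89 for 1.5 h in siHNF4A. The share of genes with the larger response in siHNF4A was 69.7% for lower genes at 24 h with the floor at the 40th percentile (75.6% reported), 65.8% for them with the 1.5 h reference, and 75.2% for higher genes with the pseudocount (69.8% reported). At 1.5 h it was 0% of 2 and of 1 lower genes with floors at the 60th and 75th percentiles. Selected on siControl, it was 36.4% (higher) and 32.9% (lower) at 24 h, and 3.45% and 3.49% at 1.5 h. Selected on siHNF4A, it was 88.1% and 92.4%, and 85.9% and 97.7%, since selection on an arm favours that arm. The correlation of the arms at 24 h (0.595) was 0.476, 0.679 and 0.745 with floors at the 40th, 60th and 75th percentiles, 0.624 with the pseudocount, 0.625 with the mean of probe sets, 0.58 without _x_at and _s_at probe sets and 0.515 with the 1.5 h reference. At 1.5 h it was -0.137 with the floor at the 75th percentile. The correlation of siRNA and TGF-beta differences (0.162) was 0.118, 0.206 and 0.244 with those 3 floors. The ribosomal and housekeeping median turned to -0.026 (siRNA), -0.040 (24 h) and -0.016 (1.5 h) under quantile normalization and to -0.022 at 24 h with the 1.5 h reference. FGA for the siRNA turned to -0.14 without _x_at and _s_at probe sets. Values that passed in neither setting also changed sign, E2F1 between arms to 0.18 with the floor at the 60th percentile, EDN1 between arms to -0.075 with the floor at the 75th, KLF10 at 24 h to 0.0046 with median scaling and MYC at 24 h to -0.030 under quantile normalization.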

Other observations

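Of the tests below, those on the interferon-response genes, on shared arrays and on other splits of the arrays were chosen after their results were seen. In the endoplasmic reticulum and integrated stress list 6 of 18 measured genes rose and 1 fell with the siRNA, and 8 and 1 adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, rose by 0.72 ± 0.15 and the chaperone gene DNAJB9 by 0.61, while TRIB3 fell by 0.38. At 24 h of TGF-beta 4 of them rose and 2 fell, or 3 and 3 without the siControl 0 h array, and 6 and 2 adjusted over the list alone, with DDIT4 at 1.80 ± 0.18 and CRELD2 at -1.21 ± 0.14. HMGCS1, an early enzyme of cholesterol synthesis, rose by 1.18 ± 0.22 with the siRNA (0.68 without the 1.5 h pair, and passing) as the 1 of 15 genes to pass in its list, as FDPS (0.53 ± 0.12) was at 24 h, both also over the list alone. Without the siControl 0 h array 1 rose and 1 fell in that list at 24 h. Of 24 glycolysis and hypoxia genes 3 rose with the siRNA, also over the list alone, or 2 with 1 falling without that array, with HK2 at 0.93 ± 0.11. Of 37 matrix and cytoskeleton genes 5 rose and 2 fell with the siRNA, or 6 and 1 without that array and 7 and 4 adjusted over the list alone. THBS1 rose by 0.98 ± 0.10 and LOX, which crosslinks collagen, fell by 0.77 ± 0.14. XBP1 (0.56), DNAJB9 (0.49) and TRIB3 (-0.23) did not pass for the siRNA without the 1.5 h pair, nor TRIB3 (-0.46) and LOX (-0.82) without the 24 h pair.

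Of 24 glucose, amino acid and urea genes 3 fell with the siRNA and none rose, or 3 and 1 both without the siControl 0 h array and adjusted over the list alone, among them MAT1A (-1.11 ± 0.23), which makes S-adenosylmethionine. Of 21 epithelial junction and keratin genes 2 rose and 2 fell with the siRNA, or 2 and 1 without that array and 4 and 3 adjusted over the list alone. Liver transcription factors passed in 1 of 19 cases for the siRNA, PROX1 at 0.42, or none over the list alone and 1 each way without that array. At 24 h 2 rose and 2 fell in both counts, or none and 3 without the siControl 0 h array. Of 13 receptors and Smads TGFBR2 rose and TGFBR3 fell by 0.33 with the siRNA, or 1 and 2 adjusted over the list alone. TGFBR3 did not pass without the 0 h pair or its siControl array (-0.24 in each), nor without the 1.5 h (-0.38) or 24 h (-0.36) pair. PROX1 did not pass without 1.5 h (0.35) or 24 h (0.40), MAT1A without 1.5 h (-0.99), nor TGFBR2 (0.46) and CD14 (-0.78) without 24 h. LEFTY1 (1.78 ± 0.35) was the 1 of 4 nodal and activin targets to rise at 24 h, and ID4 (-1.01 ± 0.27) the 1 of 4 ID genes to fall, with 1 rising and 1 falling without that array. Of 20 interferon-response genes 4 rose and 1 fell at 24 h, 6 and 1 adjusted over the list alone, and none passed without that array. In coagulation and complement SERPINC1 (-0.85 ± 0.17) alone passed at 24 h, and among acute-phase and inflammatory genes CXCL8 (2.21 ± 0.29). Without that array 2 of the former fell, and 2 of the latter rose and 1 fell. Of 6 measured blood, endothelial and fibroblast markers, at a median signal of 36.1, CD14 fell by 1.18 ± 0.29 with the siRNA and rose by 1.39 ± 0.35 at 24 h, when PECAM1 rose by 1.01 ± 0.27. Without the siControl 0 h array neither passed at 24 h (1.20 and 0.54). None of 17 ribosomal and housekeeping genes passed in any contrast.

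Among 650 genes that were at least 2-fold from 0 h at 24 h on the average of the arms, 470 (72.3%) had the larger change in siHNF4A, but genes are not independent replicates and each arm has 1 array per time. Selected on siControl alone the share was 36.4% of higher and 32.9% of lower genes. Array scaling would bring the share to 50% or below, and it was 71.7% under quantile normalization. An odd siControl 0 h array would do so once the 1.5 h arrays served as the reference, and the share was 67.6%. Noise of single probe sets would do so in other probe sets of the same genes, where 200 of 287 (69.7%) had the larger change in siHNF4A. What stays open is the HNF4A siRNA itself, which may strengthen the response, and any difference between the transfections or arrays of an siRNA, and neither was tested.

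Interferon-response genes had a median log2 difference of -0.59 between siHNF4A and siControl. The medians were -0.16 at 0 h, -0.56 at 1.5 h and -0.61 at 24 h, at percentiles 10.4, 0.03 and 0 of random lists. A single odd array would leave the median at 0 once the pair that held it was left out. It was -0.66, -0.42 and -0.43 without the 0, 1.5 and 24 h pairs, each below 0 by more than its interval. These values argue against 1 array as the whole cause. The interval measures the spread among the list's genes, which may move together, and not that between arrays. Signals near the floor also remain possible, because the 7 members with a mean above 100 had a median of -0.32 with an interval of -0.64 to 0.06, though 5 of the 7 were lower and the median lay at percentile 1.995. A response to the control siRNA could raise these genes in siControl, and without untransfected arrays in the comparison the value of -0.591 does not separate it from a fall with siHNF4A. HNF4A targeting is a further explanation that was not tested.

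Genes called for the siRNA and for 24 h of TGF-beta tended to share their direction. Noise of shared arrays that is independent between genes does not account for it. The siRNA and 24 h contrasts had a covariance of 0.0524 across genes against -0.0014 to 0.0012 for simulated unchanged genes. A pair of differences with no array in common had 0.0383 against -0.0026 to 0.0025. Noise common to many genes of an array was not simulated. No range was simulated for the 1.5 h differences of the arms, which share no array either. Their covariance of -0.0092 lay outside the ranges simulated for the other pairs. A common program of both treatments, or of the siRNA and time in culture, may add to the shared direction. That is a hypothesis found on these data and was not tested. A difference in growth state between the siRNA arms also remains untested. For the siRNA calls themselves, the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real one called 961 genes, 1 split with as many, and the highest of the others called 0. In the others much of a real siRNA effect counts as error, and some put both arrays of a time on one side. Few calls were likely there in advance, so the 0 does not compare like with like.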
